A study of Mus musculus with 6 samples.

How the data were processed

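Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in primary mouse macrophages grown from bone marrow of Fvb mice to day 7 of differentiation, per the labels. The cells were either untreated or stimulated for 2 h with lipopolysaccharide (LPS, 10 ng/ml), the outer-membrane glycolipid of Gram-negative bacteria. Chromatin fixed for 10 min in 1% formaldehyde was precipitated with antibodies to p300, to PU.1 or to histone H3 mono-methylated at lysine 4 (H3K4me1). H3K4me1 and input DNA, the sequenced chromatin without precipitation, were measured in untreated cells.

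The deposited files held aligned reads and peak lists on mouse build mm9, as named in the submitters' processing notes. Each read was a line with its position and strand, 36 bp long by its coordinates. The aligner, the treatment of reads with several hits and the peak caller's version were not given in the sources used here. Peaks were called with MACS, per the deposited column description, and the score of each peak was 10 times the -log10 p-value of the authors' caller. The lowest score in each list lay at or just above 50. Per the file headers, p300 peaks were called against a library named naked, PU.1 peaks against one named random, and H3K4me1 peaks against input. Reads of both biological replicates were merged for p300, per the series' design text, so each p300 peak list is pooled. The header line of the untreated PU.1 list names LPS, so the lists were checked against the reads. The 14146 peaks found in the untreated PU.1 list alone held 205549 reads of the untreated library and 112968 of the LPS library. The 15145 peaks found in the LPS list alone held 209123 LPS and 99952 untreated reads, so each list was used under its sample's label.

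Each p300 condition had 2 read files, replicates 1 and 2, described as different biological replicates. PU.1 in each condition, H3K4me1 and input had 1 library each, so no p-value across libraries was computed for them. Depth ranged from 5744811 reads (p300 LPS replicate 1) to 7828655 reads (p300 LPS replicate 2). Counts in this text were made here from the deposited reads, which are not a count table. A single read was kept per position and strand, 5' ends were moved 100 bp downstream, and chromosomes 1 to 19 and X were used. The offset between strands at peaks was 80 to 125 bp in the 7 precipitated libraries, so a 50 bp shift was tried as well.

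The p300 peaks of both conditions were merged into 19879 sites of median width 487 bp, and 19727 sites with at least 10 reads over the 4 p300 libraries were tested. Libraries were scaled by the median of ratios over sites. LPS and untreated libraries were compared with limma voom (limma 3.58.1, R 4.3.3) with treatment as the single term and Benjamini-Hochberg adjustment at 0.05. The fit gave all sites a common residual variance, so SE and p do not measure the spread of a site's own replicates. Normalised reads are reads divided by the scaled library size, at the geometric mean library size of the 4 libraries. The scaled size of untreated replicate 1 was 30.6% of that of untreated replicate 2. In data simulated on these sites with equal site means in all libraries, the fit recovered 4 of 100 sites changed 4-fold and 32 of 100 changed 8-fold, with 1 false call and no wrong sign. With site means that differed between replicate numbers it recovered 0 of 100 at either fold. Those means were taken from the observed counts and noise was then added, so this setting may overstate the variation between libraries. Changed sites were drawn from sites with at least 40 reads, while sites not called had a median of 32. Recovery at weaker sites was therefore not measured, and sites not called cannot be read as unchanged.

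Peak lists were compared by overlap of at least 1 bp. The share of p300 peaks at PU.1 peaks was set against 1000 circular shifts of the p300 peaks along their chromosomes. Shares of sites carry exact (Clopper-Pearson) 95% binomial intervals, and ratios between 2 libraries carry exact 95% intervals conditional on their sum. These intervals cover counting error only. Classes of p300 sites were compared by Fisher's exact test across sites, with Benjamini-Hochberg adjustment over 6 tests. This test treats sites as independent, which neighbouring sites may not be, and does not measure spread between libraries. Medians were placed among 10000 random lists of sites not called, matched on reads in 20 bins. H3K4me1 was expressed as the log2 ratio to input within 1 kb of the site centre, after depth scaling and with 1 read added to each, and PU.1 ratios at p300 sites had 0.5 reads added. The overlap code equalled brute force in 50 of 50 simulated sets, and 2 of 100 simulated lists without effect fell outside the central 95% of random lists. Python 3 with numpy, pandas and scipy was used for these steps.

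Named p300 sites were the 5 largest rises and 5 largest falls among called sites with at least 40 reads whose libraries did not overlap between conditions. Named PU.1 sites were the 5 largest rises and falls with at least 40 reads whose exact interval lay beyond 2-fold. The designs, the rule for named sites and most alternatives were fixed before the data were examined. The alternatives were other scalings, read filters, windows, shifts and overlaps, the limma-trend test, a replicate block and leaving out each p300 library. Genes, transcription start sites and motifs were not analysed here because the annotation at hand (GRCm38.p6) is of another build, so sites are given by mm9 coordinates.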

Results

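The study mapped candidate enhancers in macrophages and how they change when the cells meet LPS, by locating p300, PU.1 and H3K4me1. p300 is a histone acetyltransferase recruited to active enhancers, PU.1 is a transcription factor of the ETS family needed for the macrophage lineage, and H3K4me1 is a histone mark of enhancers. Primary macrophages were untreated or treated with LPS for 2 h. p300 had 2 replicates per condition, and PU.1 in each condition, H3K4me1 and input had 1 library each. The libraries held 5744811 to 7828655 aligned reads. The p300 replicates differed in enrichment. In the p300 peaks of their own condition lay 1.44% of the reads of untreated replicate 1 and 6.20% of those of replicate 2, and 2.31% and 5.49% of those of LPS replicates 1 and 2. Input had 0.872% and 0.875% of its reads in the 2 p300 lists. PU.1 libraries had 51.7% (untreated) and 49.2% (LPS) of their reads in their own peaks, and H3K4me1 had 55.2%.

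The first comparison asked where p300 binding changed within 2 h of LPS. Of 19727 p300 sites tested, 388 gained p300 and 42 lost it. Of the 388 gained sites, 366 overlapped a p300 peak in the LPS list alone and 22 a peak in both lists, while 41 of the 42 lost sites overlapped a peak in the untreated list alone. The median log2 fold change was 2.58 at gained sites and -2.31 at lost sites. Within replicate numbers the gained sites, which were chosen on these same libraries, had a median log2 ratio of 1.51 for replicate 1 and 3.06 for replicate 2. Pearson's r between the log2 ratios of the replicate pairs was 0.284 over the 4619 sites with a p300 peak in both lists. Sites are not replicates, and this class held 22 of the 388 gained and 1 of the 42 lost sites. It leaves out most called changes, so r may differ over all sites.

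The site with the largest rise lay on chromosome 2 from 144539980 to 144541271, with 1.78 ± 0.107 normalised p300 reads in untreated cells and 128 ± 38.0 after LPS (mean ± SD, n = 2 each). Its log2 fold change was 5.81 ± 1.00 (SE; limma voom, adjusted p = 1.25e-05). At this site PU.1 went from 15 to 91 reads between the untreated and the LPS library. SE and p of the fit rest on a variance common to all sites, not on the SD shown. On chromosome 9, from 14612383 to 14613713, p300 rose from 5.22 ± 5.77 to 73.4 ± 9.59 normalised reads (SD, n = 2 each; log2 fold change 5.11 ± 0.77, SE, limma adjusted p = 4.22e-07), and PU.1 reads went from 6 to 54. The other 3 of the 5 largest rises had 1 or 2 untreated reads in all. On chromosome 17, from 32861157 to 32861742, 1 untreated and 70 LPS reads gave a scaled ratio of 72.2 (exact 95% interval 12.5 to 2894). Chromosome 10, from 53004740 to 53005554, had 2 and 89 reads, a ratio of 45.9 (12.3 to 385). Chromosome 19, from 16116391 to 16116984, had 1 and 58 reads, a ratio of 59.9 (10.3 to 2405). Adjusted p by limma at these 3 sites was 0.00635, 0.00519 and 0.00963. Single libraries moved some of these folds: without untreated replicate 2 the log2 fold change was 2.66 at the chromosome 9 site and 2.97 at the chromosome 19 site (4.95 with all libraries), and without untreated replicate 1 it was 6.38 at the latter.

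The named losses were smaller. On chromosome 13, from 94762312 to 94762901, normalised p300 reads went from 21.2 ± 3.76 to 2.50 ± 2.61 (SD, n = 2 each; log2 fold change -3.65 ± 1.03, SE, limma adjusted p = 0.0271). On chromosome 4, from 94879490 to 94880206, they went from 22.2 ± 12.9 to 2.10 ± 1.13 (log2 fold change -3.34 ± 0.99, limma adjusted p = 0.0409), and PU.1 went from 35 to 7 reads. The site on chromosome 4 from 19822233 to 19822683 had 61 untreated and 3 LPS reads, a scaled ratio of 0.0508 (0.0102 to 0.155; limma adjusted p = 0.0463). The remaining named losses lay on chromosome 10 from 98632395 to 98632873 (log2 fold change -2.73) and on chromosome 7 from 20278528 to 20279317 (-2.72), with limma adjusted p of 0.0454 and 0.0344. Without LPS replicate 2 the log2 fold change was -1.90 at the chromosome 13 site, -2.25 at 94879490 on chromosome 4, -0.83 on chromosome 10 and -1.33 on chromosome 7. At the chromosome 13 site it was -4.35 without LPS replicate 1, and at 94879490 on chromosome 4 it was -4.01 without untreated replicate 1. All 10 named sites had PU.1 read counts that moved in the same direction as p300.

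**Figure D1:**
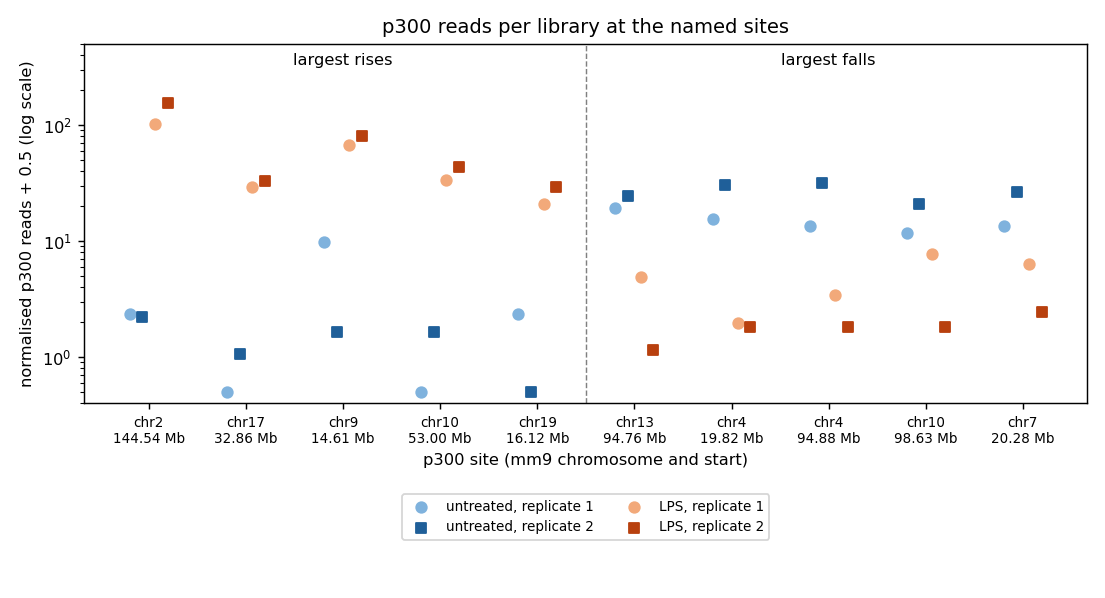
Normalised p300 reads plus 0.5 (log axis) in each of the 4 p300 libraries at the 5 sites with the largest rise (left) and the 5 with the largest fall (right); points are single libraries. At the chromosome 2 site the LPS libraries hold 101.4 and 155 normalised reads and the untreated libraries 1.86 and 1.71.

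These calls depended on the scaling and on single libraries. With total reads as library size limma voom called 0 sites (smallest adjusted p 0.583). There 1494 sites had an unadjusted p under 0.05, 1027 of them higher. With background bins it also called 0 sites (1449 at unadjusted p under 0.05, 956 higher). All 388 and 42 called sites kept their direction, but their folds were large beside the shifts given next, so this was likely in advance. The errors at the called sites grew more than the folds moved: at gained sites the median log2 fold change was 2.58 (median SE 0.63) and became 2.43 (1.33) with total reads and 2.41 (1.45) with background bins, at lost sites -2.31 (0.63) became -1.85 (1.30) and -1.86 (1.43), and the median of all sites moved to 0.20 and 0.16. Calls higher and lower numbered 488 and 356 without untreated replicate 1, 33 and 695 without untreated replicate 2, 88 and 0 without LPS replicate 1, and 147 and 0 without LPS replicate 2, so the ratio of gains to losses is not settled by these libraries.

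The deposited p300 peak lists overlapped in part. Of 12421 untreated p300 peaks, 4729 (38.1%, exact 95% interval 37.2 to 38.9) overlapped an LPS peak, and of 12237 LPS peaks 4669 (38.2%, 37.3 to 39.0) overlapped an untreated peak. Shared peaks were mostly strong ones. With each list cut into 4 equal groups by the authors' score, in the weakest group of the untreated list 12.7% were shared (11.5 to 13.9), in the strongest 79.3% (77.8 to 80.7), and in the LPS list 13.6% and 69.2%. PU.1 peaks overlapped far more, with 59354 of 73500 untreated peaks (80.8%, 80.5 to 81.0) and 59220 of 74365 LPS peaks (79.6%, 79.3 to 79.9) shared. Each list stands for 1 pooled or single measurement, so no test was made. The p300 libraries were far less enriched than those of PU.1, so the lower p300 share does not show a larger response to LPS.

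Within PU.1 sites the reads of the untreated and LPS libraries were close. Of 42940 sites with at least 40 reads, 40587 (94.5%) had a ratio within 2-fold. The exact interval of the ratio lay beyond 2-fold higher at 242 sites and beyond 2-fold lower at 23. The site on chromosome 12 from 27126600 to 27127492 had 1 untreated and 49 LPS reads (ratio 49, 8.39 to 1974), and p300 there had 3 and 6 reads in the untreated replicates and 33 and 111 in the LPS replicates. On chromosome 5, from 92774672 to 92775702, PU.1 had 3 and 63 reads (ratio 21, 6.87 to 105). The other 3 of the 5 largest rises, on chromosome 11 (33675699 to 33676109), 16 (84720909 to 84721417) and 12 (17111890 to 17112420), had 1 untreated read and 42, 42 and 39 LPS reads (ratios 42, 42 and 39; lower bounds 7.14, 7.14 and 6.60, upper bounds 1698, 1698 and 1579).

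The PU.1 site with the largest fall, on chromosome 2 from 163054629 to 163055282, had 52 untreated and 8 LPS reads (ratio 0.154, 0.0631 to 0.326), and p300 had 9 and 39 reads in the untreated and 3 and 5 in the LPS replicates. Next came chromosome 10, 41964373 to 41964822 (47 and 8 reads, ratio 0.170), chromosome 5, 64727941 to 64728751 (46 and 8, 0.174), chromosome 6, 146111075 to 146111651 (36 and 7, 0.194), and chromosome 1, 137526333 to 137526751 (34 and 7, 0.206). Of the 242 PU.1 sites that gained reads, 55.4% (48.9 to 61.7) overlapped an LPS p300 peak and 5.37% (2.89 to 9.01) an untreated p300 peak, against 14.1% and 16.4% of the 42675 PU.1 sites whose interval did not lie beyond 2-fold. The comparison is between 2 libraries, not between conditions, and with all reads kept 419 and 77 sites passed the bounds.

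p300 peaks lay at PU.1 peaks in both states. Of untreated p300 peaks, 7369 (59.3%, exact 95% interval 58.5 to 60.2) overlapped an untreated PU.1 peak, and of LPS p300 peaks 6643 (54.3%, 53.4 to 55.2) overlapped an LPS PU.1 peak. Shifted p300 peaks overlapped PU.1 peaks in 2.97% and 3.27% of cases on average and in 3.49% and 3.898% at most (one-sided permutation p = 0.001 in both states, the smallest that 1000 shifts can give). Among the strongest of the 4 groups of p300 peaks the shares were 88.7% untreated and 83.2% after LPS, and among the weakest 32.2% and 27.9%. H3K4me1 peaks of untreated cells overlapped 56.3% of untreated and 50.7% of LPS p300 peaks.

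The next question was whether PU.1 already occupied, before LPS, the sites that later gained p300. An untreated PU.1 peak overlapped 199 of the 388 gained sites (51.3%, 46.2 to 56.4), close to the 48.8% of 19297 sites not called (odds ratio 1.11, Fisher's exact test, two-sided, p = 0.330, adjusted 0.330). Another 76 gained sites overlapped a PU.1 peak after LPS only, and 113 (29.1%) overlapped none. Lost sites carried PU.1 before LPS in 35 of 42 cases (83.3%, 68.6 to 93.0). Their odds ratio was 5.26 (Fisher's exact p = 6.54e-06, adjusted 1.31e-05). These tests take sites as independent, and their p-values do not measure spread between libraries.

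The sites not called were weaker, with a median of 32 p300 reads against 75 at gained sites. Among random lists of sites not called matched on p300 reads, a comparison chosen after seeing the data, the median share with untreated PU.1 was 82.5% (95% of lists 78.6 to 86.1), and gained sites lay below all 10000 lists. Lost sites lay at percentile 49.7 of such lists. The matching used p300 reads of both conditions together, and 366 gained sites had a p300 peak in the LPS list alone. Matched sites thus held more p300 before LPS, and a lower share with untreated PU.1 can follow from how gained sites were chosen. Peaks of the LPS list alone carried untreated PU.1 in 30.7% of cases and peaks in both lists in 84.7% (odds ratio 0.0797). Peaks in both lists have an untreated p300 peak by definition and were stronger, with a median of 92 p300 reads against 21. This difference can therefore follow from how these classes were drawn. With the site centre within 100 bp of a PU.1 peak, the odds ratio of gained sites was 0.90 (p = 0.329, Fisher's exact test). Neither this nor the main odds ratio set gained sites apart from sites not called.

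**Figure D2:**
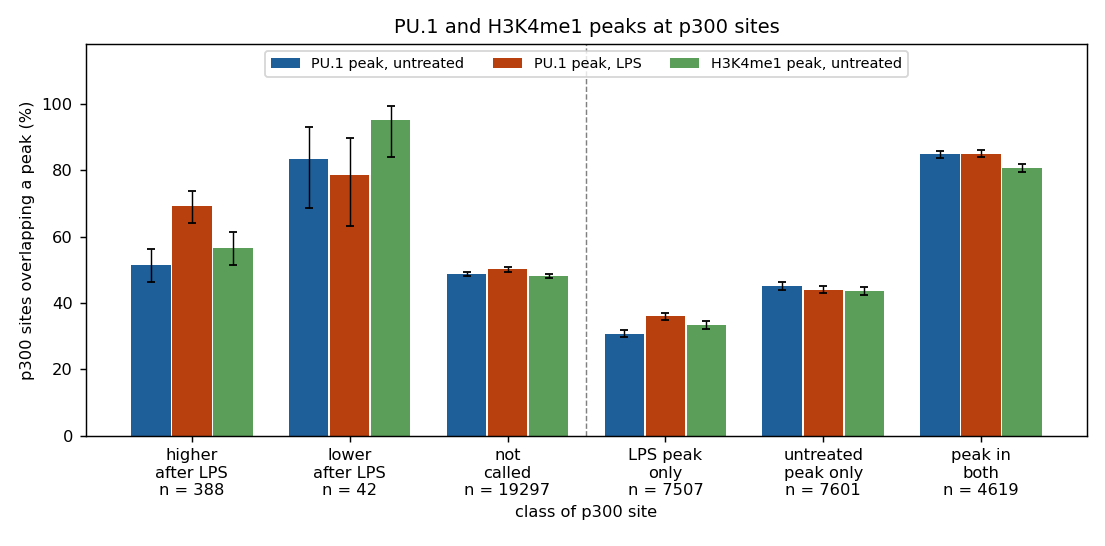
Percent of p300 sites (y axis) that overlap a PU.1 peak of untreated cells, a PU.1 peak after LPS or an H3K4me1 peak of untreated cells, for sites gained, lost or not called and for sites by the deposited p300 lists; error bars are exact 95% binomial intervals. Gained sites overlap PU.1 peaks in 51.3% before and 69.1% after LPS, and sites with a p300 peak in both lists in 84.7% and 85.0%.

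PU.1 and p300 reads moved together at changed sites. The median log2 ratio of PU.1 reads, LPS to untreated, was 1.37 at gained p300 sites (quartiles 0.71 and 2.16), with 372 of 388 above 0. It was -0.54 at lost sites (-1.14 and -0.20) and 0.00 at sites not called. Gained sites lay above, and lost sites below, all 10000 random lists matched on PU.1 reads (medians of lists 0.08 and 0.03). Across 9429 p300 sites with at least 40 PU.1 reads, Pearson's r between the log2 changes of p300 and PU.1 was 0.595 and Spearman's rho 0.547, and across the 4038 with a p300 peak in both lists they were 0.458 and 0.422. Sites are not independent replicates, and PU.1 had 1 library per condition. Among gained sites the pooled PU.1 ratio was 2.99 at the 113 without a PU.1 peak and 1.85 at the 199 with an untreated one. Reads that strong sites bring into any precipitated LPS library may account for part of this rise, as described further below. In the replicate 2 pair alone, chosen after seeing the data, the 547 sites past 2-fold higher had a median PU.1 log2 ratio of 0.96. The 41 such sites of the replicate 1 pair had 0.86. Of these sites, 277 and 33 were also among the gained sites. The PU.1 libraries were the same, so these medians are not separate evidence.

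**Figure D3:**
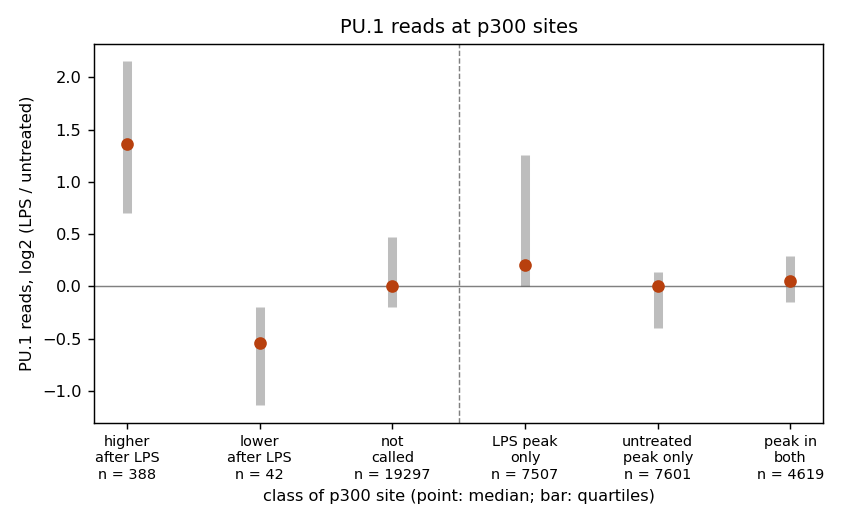
Log2 ratio of PU.1 reads, LPS to untreated (y axis), at p300 sites of each class (x axis); points are medians and bars span the quartiles over sites. Gained p300 sites have a median of 1.37, lost sites -0.54 and sites not called 0.00.

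H3K4me1 before LPS also differed between gained and lost sites. An H3K4me1 peak overlapped 219 of 388 gained sites (56.4%, 51.3 to 61.4) and 40 of 42 lost sites (95.2%, 83.8 to 99.4). Among sites not called the share was 48.1%. The odds ratios were 1.40 and 21.6 (Fisher's exact p = 0.00121 and 8.76e-11, adjusted 0.00181 and 2.63e-10). Sites are not independent replicates, so these p-values do not measure spread between libraries. Many gained sites were wider than the 487 bp median of all p300 sites, and overlap by 1 bp favours wide sites. Width was not matched and may add to the gained share. The median log2 ratio of H3K4me1 to input within 1 kb was 1.57 at gained sites, 2.67 at lost sites, 1.38 at sites not called and 1.196 at 63559 untreated PU.1 peaks without p300. Matched on p300 reads, the median of random lists was 2.29 for gained sites, which lay below all 10000 lists, and 2.30 for lost sites, which lay at percentile 99.04. Lost sites fell within the central 95% of lists over 500 bp on each side (percentile 97.44) and with all reads kept (97.27), and above it over 2 kb (99.69). Their share with an H3K4me1 peak lay at percentile 99.8 (median of lists 81.0%). The share of gained sites with an H3K4me1 peak also lay below all matched lists (median 80.2%). The direction against sites not called thus turned with matching. The sites matched to gained sites held more p300 before LPS, as for PU.1 above, so this turn can follow from how gained sites were chosen. Lost sites were chosen the other way, and 41 of the 42 had a p300 peak in the untreated list alone. Sites matched to them thus held less p300 before LPS. The higher H3K4me1 at lost sites can therefore also follow from how they were chosen. H3K4me1 and input had 1 library each, without LPS.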

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

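No test of a cause was made for the values in this part. Reads on sequences outside chromosomes 1 to 19 and X were not used in the comparisons, and in both replicate 1 libraries of p300 some of them lay above input, which was the control. Sequences of the Y chromosome held 0.00314% of distinct reads of untreated replicate 1 (202 reads, exact 95% interval 0.00272 to 0.00360) and 0.00221% of LPS replicate 1 (122 reads, 0.00184 to 0.00264), against 0.00134% of input (81 reads, 0.00106 to 0.00166). Other unplaced sequences held 0.132% and 0.135% of distinct reads in these libraries, against 0.109% in input (0.107 to 0.112). The replicate 2 libraries of p300 held 0.0927% and 0.0972% on those sequences, below input.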

How the results depend on the processing

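The 10 named p300 sites and 10 named PU.1 sites kept their direction under each alternative that could be computed. Their naming rules, with libraries apart between conditions or intervals beyond 2-fold, make that likely in advance. p300 sites lost their call under some alternatives, all 10 with total reads or background bins as library size. There their folds moved by up to 1.70 and 1.67 times (over 1.5 times at 3 and 2 sites). At 98632395 on chromosome 10, -2.73 on the log2 scale became -1.96 and -1.99. limma-trend, with its prior count of 2, moved all 10 folds over 1.5 times (up to 3.02), and leaving out untreated replicates 1 and 2 and LPS replicates 1 and 2 moved 2, 2, 1 and 4 of them (up to 5.44). p300 calls (388 higher, 42 lower) became 0 and 0 by limma voom with total reads or background bins (1494 and 1449 sites at unadjusted p under 0.05), 76 lower with all reads kept, 60 and 0 over 500 bp around the centre, 1208 and 449 at a sum of at least 40 reads, 1249 and 419 with the upper 50% of peaks by score, and 1171 and 271 at sites with a PU.1 or H3K4me1 peak. Fewer sites were tested in the last 3 of these. Leaving out each p300 library gave 33 to 488 higher and 0 to 695 lower; the lone library left in a condition is assumed to vary like the others. With the replicate number as a block, 896 and 395 sites were called (69.4% higher; 49.9% of 5286 at unadjusted p under 0.05), including 364 and 40 of the calls without the block; same-numbered libraries deviated together (r = 0.274), but 2 pairs that share only a file number do not establish pairing. The replicate 2 pair alone had 547 sites past 2-fold higher and 180 lower. Shared p300 peaks were 33.4% and 33.9% (untreated, LPS) at an overlap of 50% of both peaks, 48.9% and 49.1% in the stronger 50% of peaks and 51.7% and 55.9% among peaks with a PU.1 or H3K4me1 peak; shared PU.1 peaks were 74.5% and 73.6%, and 83.6% and 82.6%, in the first 2 of these settings. PU.1 sites past 2-fold numbered 419 and 77 with all reads kept. The odds ratio for untreated PU.1 at gained p300 sites was 1.11, and 0.90 with the site centre near a PU.1 peak. Neither set gained sites apart from sites not called (Fisher's exact p = 0.330 and 0.329). The odds ratio was 0.0797 for LPS-only against shared peaks and 0.224 against sites matched on p300 reads. Shared and matched sites held more p300 before LPS. The median PU.1 log2 ratio at rising p300 sites was 0.86 in the replicate 1 pair and 0.96 in the replicate 2 pair. Median log2 H3K4me1 over input was 1.27 at gained sites within 2 kb and 2.47 at lost sites within 500 bp, where lost sites fell to percentile 97.44 of matched lists, as with all reads kept (97.27), from 99.04. Except where the construction is named, the cause was not tested. The restriction to sites or peaks with PU.1 or H3K4me1, the replicate pairs alone and the matched sites were chosen after seeing the data. The alternative count tool was not run, nor were gene distance, gene lists and motifs with their alternatives. Simulated recovery of 4-fold and 8-fold changes was 4 and 32 of 100 with equal site means (11 and 51 with the block). It was 0 and 0 with site means that differ by replicate number (10 and 64 with the block). Changed sites were drawn from those with at least 40 reads, and recovery was not split by reads per site.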

Other observations

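The tests on single replicate pairs, on the weak untreated replicate, on peaks without PU.1 or H3K4me1, on PU.1 reads at sites without a PU.1 peak and on H3K4me1 at changed PU.1 sites were chosen after the results were seen. The test on closeness of gained sites and that on scaling with all 4 libraries were set out beforehand.

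Gained p300 sites lay close together. Of 388, 115 (29.6%) had another gained site within 50 kb, against a mean of 8.49% and at most 15.2% in 1000 random lists of LPS-peak sites matched on p300 reads. On chromosome 12, 9 gained sites lay between 27123941 and 27163933, where p300 reads went from 141 to 1190 and PU.1 reads from 92 to 448. On chromosome 11, 8 gained sites lay between 83338727 and 83364901 (134 to 1206 p300 reads, 234 to 680 PU.1 reads), of which 3 had a PU.1 peak before and 6 after LPS. On chromosome 14, 5 lay between 103414676 and 103458907 (126 to 633 p300 reads). In all, 13 groups of at least 3 gained sites were found. Some neighbours may be pieces of the same enriched region: on chromosome 2 a gained site ended at 62484037 and another began at 62484044. Such pieces would change together, and the random lists were matched on reads only. Split peaks may therefore give part of the excess. A hypothesis is that p300 gain after LPS may occur over neighbouring elements as a unit, which these counts do not test further.

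PU.1 sites that changed differed in H3K4me1 before LPS. At the 242 sites that gained PU.1 reads, the median log2 H3K4me1 over input was 1.504, at percentile 1.99 of random lists matched on PU.1 reads (median 1.72). At the 23 sites that lost reads it was 2.56, at percentile 99.97 (median of lists 1.73). The matching used PU.1 reads of both libraries together, while H3K4me1 was measured before LPS only. By selection, sites that gained PU.1 reads had relatively few before LPS, and sites that lost them relatively many. Either percentile may therefore follow from PU.1 before LPS. A candidate hypothesis is that PU.1 gain with LPS favours regions with less of the mark and loss favours marked regions; the first difference is small, and each mark had 1 library.

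More p300 sites were called higher than lower, 90.2% of all calls. Without untreated replicate 1, 343 of the 388 gained sites (88.4%) were still called. The 388 had been chosen with the remaining libraries too, and only untreated replicate 2 was left for that state. This retention therefore cannot decide whether the gained sites came from weak enrichment of untreated replicate 1. Whether it shapes the balance stays open: the share of higher calls was 57.8% without it, through 356 lower calls, and 4.53% with it alone for the untreated state, but in the replicate 1 pair 41 sites rose past 2-fold and 1 fell, and in the replicate 2 pair 547 and 180. With total reads as library size these were 120 and 0, and 417 and 326, but within a pair another library size moves every log ratio alike. With all 4 libraries and treatment as the single term, the share higher at unadjusted p under 0.05 was 68.7% with total reads and 65.3% with the median of ratios, both under the bound of 75% set for that test, so the scaling stays open, as does a response to LPS made mostly of gains.

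Of the p300 peaks, 3768 untreated (30.3%) and 4318 LPS (35.3%) overlapped neither a PU.1 nor an H3K4me1 peak. Of the tested sites of this kind, 3429 had a peak in the untreated list alone and 4040 in the LPS list alone. Chance clusters of reads are argued against, since p300 reads of the other condition there were 3.17 (3.04 to 3.32) and 2.64 (2.55 to 2.74) times those expected from input. Input reads there were 0.860 times the genome mean (0.838 to 0.882), so a high density of input is argued against. PU.1 reads were raised, at 1.91 and 1.89 times input (untreated, LPS) at the untreated-only sites and 1.47 and 2.37 times at the LPS-only sites, while H3K4me1 reads were 1.00 (0.945 to 1.06) and 1.29 times input by total depth, against 0.229 times in bins without any peak (PU.1 0.366 and 0.402). Weak p300 binding in both conditions, weak PU.1 binding with it and regions that come down with any antibody may each give such values and stay open, and GC content was not tested here.

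PU.1 reads rose at gained p300 sites, also where no PU.1 peak was called. At the 113 gained sites without a PU.1 peak, PU.1 reads went from 793 to 2373 (ratio 2.99, 2.76 to 3.25), and at the 199 with an untreated PU.1 peak from 10110 to 18688 (ratio 1.85, 1.80 to 1.89). At sites not called the ratio was 1.03. Reads that strong sites bring into any precipitated LPS library may thus account for part of the PU.1 rise, and PU.1 binding below the callers' threshold would give the same values. LPS-treated input or an unrelated antibody, which would separate these, was not analysed here.

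Reads on chromosome X made up 4.19% of input, 1.69% of H3K4me1, and 2.42% and 2.49% of untreated and LPS PU.1 reads. In p300 they were 3.49% and 2.85% of untreated replicates 1 and 2 and 3.55% and 2.78% of LPS replicates 1 and 2, and 1.505% of H3K4me1 peaks lay on it.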
